A study of Homo sapiens with 4 samples.

How the data were processed

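Total RNA from wild-type HT1080 cells, an established human fibrosarcoma line, was sequenced in 4 libraries that form 1 group of 4 replicates. Per the labels' protocols, the RNA came from frozen cell pellets, ribosomal RNA was removed by depletion, and fragments were read from both ends. No second condition is part of the series, so the comparisons made here are between genes within a library and between the replicates. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

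The authors deposited 1 table of expected counts per gene, the estimated counts that RSEM gives, which need not be whole because reads that fit several genes are divided between them. Per the submitters' processing notes, the tools were Trimmomatic 0.39, Bowtie2 2.5.4, RSEM 1.3.3 and DESeq2 1.46.0, with the genome build GRCh38. The annotation release, the strand setting and the parameters are not given in the sources used here. The table had 60675 rows, and between 6977 and 7367 values per library were not whole. The library totals were 26238346, 32336468, 32062421 and 33644204 counts for replicates 1 to 4. A floor of 3 counts therefore corresponded to between 0.0892 and 0.114 CPM in 1 library and to 0.0241 CPM over the 4 libraries together. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

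Gene identifiers were matched to GENCODE 29 (GRCh38) for gene type, position and length. This matched 57055 rows. The 3620 unmatched rows held between 0.121% and 0.133% of the counts, and no length or gene type was used for them. Because the authors' annotation release is not stated, the lengths may differ from those behind the deposited table. CPM values were computed here by scaling the deposited expected counts to the library total. A gene was called detected at 1 CPM or more in all 4 libraries. For comparisons between genes, a length-scaled abundance was computed as counts per kilobase of the union of a gene's exons, scaled to the same sum in each library over genes with a length. Short RNAs take a large part of that sum, so this abundance was used only for ranks, ratios and shares. The median percentile of a list was taken over all its members, whether detected or not. Ratios between genes were taken as log2 within each library and tested with an exact two-sided sign-flip test over the 4 libraries, which cannot give a p below 0.13. Some genes share reads with near-identical copies or with overlapping or antisense genes, and their values are uncertain.

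Expected counts were rounded to whole numbers for the count models. edgeR 4.0.16 (R 4.3.3) was run with TMM factors and its expression filter, which kept 16442 genes. The biological coefficient of variation came from an intercept-only fit. Each of the 3 splits of the libraries into 2 against 2 was tested with the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Genes more variable than the trend were found by comparing each gene's quasi-dispersion with the fitted prior trend by an upper-tailed F distribution with the same adjustment. Both tests were tested on simulated data drawn from the means and library sizes of the 16442 genes, with 200 genes changed. All simulated genes had 1 common dispersion, so the simulation does not show how the tests behave where genes differ in spread. With no gene changed, neither test called a gene. The splits called 76% of genes changed 1.5-fold and 94% of genes changed 2-fold, with 3 and 9 unchanged genes called. The test for variable genes called 76.5% and 86% of genes changed 1.5-fold and 2-fold in 1 library, with 2 and 1 unchanged genes called. The simulated coefficient of variation of 0.0374 was recovered as 0.0372. Agreement of the libraries was described by correlations of log2(CPM + 1) across the 30930 genes with any count, and pairs were compared by a chi-square test of their counts over genes with a summed count of at least 10.

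The gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The lists held 364 genes in 27 groups, of which 355 were matched by symbol and 9 by the gene identifier of the current symbol, where the table gave the symbol to no row, to several rows or to a row without a GENCODE 29 entry. The last applied to RN7SL2, whose match was corrected after its values were seen. The 18 lysine deacetylases, in 5 classes, were the main list. The other 22 lists covered acetylation partners, cancer-related pathways, reference genes, RNA classes and markers of other cell types. The rule named all deacetylases, the 10 genes with the highest mean CPM, and the 3 members of each other list with the highest length-scaled abundance. It also named up to 5 detected members of lists of other cell types, up to 3 undetected members with the lowest CPM of each remaining list, and the 10 genes with the lowest p among those more variable than the trend. Some genes that the rule names are not reported here. Genes named outside this rule are said to be chosen after their values were seen. Alternatives were other detection thresholds, normalizations, length definitions, pseudocounts, filters and DESeq2 1.42.0, and each replicate was left out in turn. The transcript that APPRIS marks as principal was added as a length after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Sequence variants and transcript isoforms were not analysed here.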

Results

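RNA abundance was measured in 4 replicate libraries of wild-type HT1080 fibrosarcoma cells by sequencing of ribosome-depleted total RNA. The libraries held between 26238346 and 33644204 expected counts. Of 30930 genes with any count, 13895 were detected at 1 CPM or more in every library, 11941 of them protein-coding. Values are given as mean ± SD over the 4 libraries unless said otherwise.

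The first question was which lysine deacetylases, the enzymes that remove acetyl groups from histones and other proteins, these cells express. Transcripts of 17 of the 18 deacetylase genes were detected. HDAC2 and HDAC1, catalytic subunits of several nuclear corepressor complexes, had the most counts, at 202 ± 7.10 and 143 ± 3.62 CPM (SD, n = 4). The class IIa genes HDAC9 and HDAC7 followed at 69.8 ± 1.70 and 68.6 ± 2.08 CPM, then HDAC3 at 44.5 ± 1.14 CPM and the sirtuin SIRT1, an NAD-dependent deacetylase, at 40.7 ± 0.893 CPM. HDAC5 was at 36.5 ± 1.72 CPM, HDAC6, which deacetylates tubulin, at 23.2 ± 0.555 CPM, HDAC4 at 22.8 ± 1.01 CPM and HDAC10 at 20.7 ± 0.720 CPM. The remaining sirtuins detected lay between 12.0 ± 1.05 CPM for the mitochondrial SIRT3 and 20.6 ± 1.02 CPM for SIRT5, with SIRT2 at 16.2 ± 1.55, SIRT7 at 18.2 ± 0.646 and SIRT6 at 19.7 ± 0.947 CPM. HDAC8 reached 14.6 ± 0.902 CPM and HDAC11, the only class IV member, 2.30 ± 0.373 CPM. SIRT4, a mitochondrial sirtuin, had 5 counts in the 4 libraries together, or 0.0378 CPM with an exact Poisson interval of 0.0131 to 0.0939 CPM (95%). For the 17 detected genes the coefficient of variation between libraries lay between 2.19% and 16.2%.

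**Figure D1:**
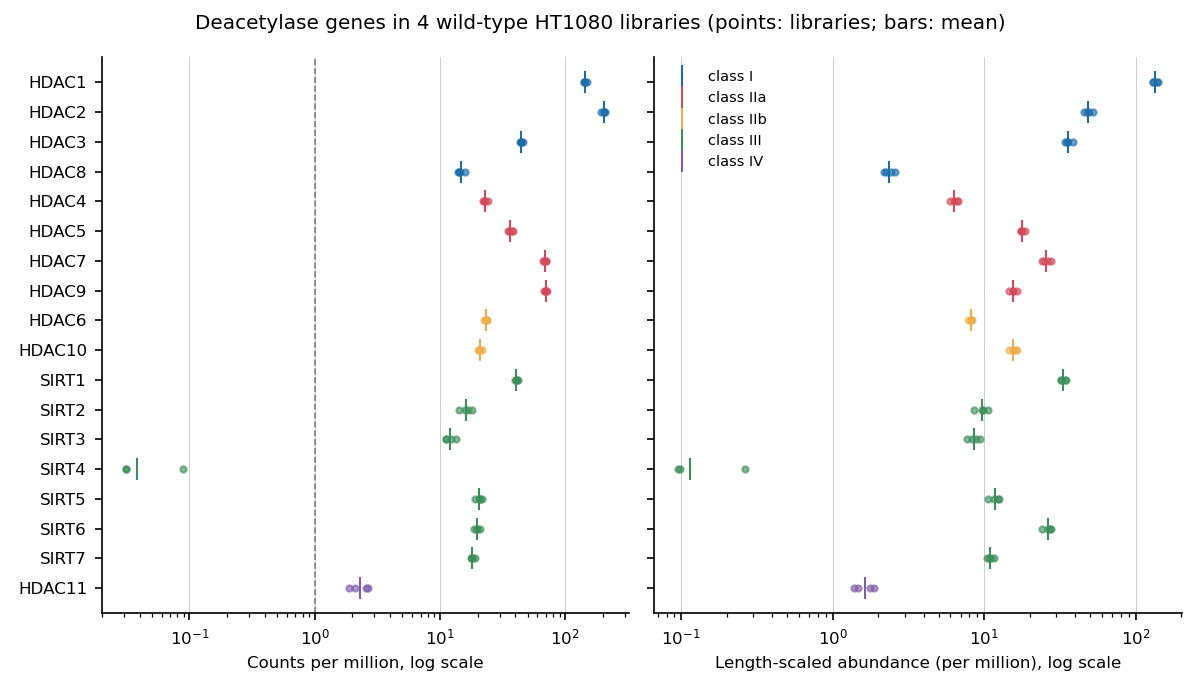
CPM (left) and length-scaled abundance (right) of the 18 deacetylase genes, on log axes, with a point for each of the 4 libraries, a bar at the mean and colours for the classes; a library with a count of 0 has no point. The dashed line marks 1 CPM, and SIRT4, at 0.0378 CPM, is the only gene left of it.

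Per kilobase of exon, HDAC1 was the most abundant deacetylase transcript, at 135 ± 5.34 (n = 4), which lay above 91.9% of the detected protein-coding genes. The median of the 18 genes lay at percentile 33.3, or at 52.6 among all protein-coding genes with any count. HDAC2 followed at 48.8 ± 2.58, HDAC3 at 35.9 ± 1.87, SIRT1 at 33.4 ± 1.41, SIRT6 at 26.4 ± 1.59 and HDAC7 at 25.8 ± 1.47. HDAC1 kept its place under all 3 length definitions, but the order after it did not: with the longest or the APPRIS transcript as the length HDAC3 exceeded HDAC2, by a log2 ratio of 0.15 ± 0.05, and with the APPRIS transcript HDAC9 rose from rank 9 to rank 3. These comparisons were chosen after the values were seen. HDAC1 (ENSG00000116478; GRCh38 chromosome 1, 32292086 to 32333635) has an exon union of 3963 nt, and HDAC2 (ENSG00000196591; chromosome 6, 113933028 to 114011308) one of 15461 nt. The log2 ratio of HDAC1 to HDAC2 was 1.47 ± 0.05, a fold of 2.77. Without length scaling the order turned, with a log2 ratio of -0.49 ± 0.05. HDAC1 exceeded HDAC3 by a log2 ratio of 1.91 ± 0.06, and HDAC3 exceeded HDAC8 by 3.92 ± 0.09. Among class IIa genes, the ratio of HDAC4 to HDAC5 was -1.49 ± 0.07 and that of HDAC7 to HDAC5 0.53 ± 0.11. HDAC6 lay below HDAC10, at -0.94 ± 0.04, and this order also turned without length scaling, to 0.16 ± 0.04. Among sirtuins, the log2 ratio was 1.79 ± 0.17 for SIRT1 to SIRT2, 1.26 ± 0.08 for SIRT6 to SIRT7 and -0.46 ± 0.12 for SIRT3 to SIRT5.

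Each of the 9 ratios had 1 sign in all 4 libraries and exceeded its SD. The exact two-sided sign-flip test gave p = 0.13 for each, before and after Benjamini-Hochberg adjustment over the 9 pairs, which is the smallest p that this test allows with 4 libraries. With the APPRIS principal transcript as the length, chosen after the data were seen, the folds of SIRT1 over SIRT2 and SIRT6 over SIRT7 fell from 3.45 to 1.28 and from 2.40 to 1.15, while that of HDAC7 over HDAC5 went from 1.44 to 2.44. The fold of HDAC3 over HDAC8 went from 15.2 to 8.87 with that length and with the longest transcript, and to 3.05 without length scaling, where SIRT6 over SIRT7 was 1.09 and HDAC4 over HDAC5 0.625 in place of 0.356. The ratio of SIRT3 to SIRT5 was -0.05 ± 0.12 with the longest transcript as the length, which is within the spread between replicates.

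By class, class I (HDAC1, HDAC2, HDAC3 and HDAC8) took 53.6% ± 0.713 (SD, n = 4) of the summed length-scaled abundance of the 18 genes. The sirtuins of class III took 24.4% ± 0.462, class IIa (HDAC4, HDAC5, HDAC7 and HDAC9) 15.8% ± 0.247, class IIb (HDAC6 and HDAC10) 5.75% ± 0.117 and HDAC11 0.393% ± 0.0629. In counts without length scaling, class IIa, at 25.5%, exceeded class III, at 16.4%.

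Transcripts of the complexes around these enzymes were present nearly throughout. Of 29 partners of deacetylase complexes, 28 were detected, with a median at percentile 65.6 of length-scaled abundance among detected protein-coding genes. TBL1XR1, a subunit of the NCoR and SMRT complexes, was at 511 ± 18.1 CPM (n = 4), and the NuRD subunits CHD4 and MTA2 were at 440 ± 13.3 and 111 ± 5.20 CPM. RCOR2, a CoREST subunit, was not detected, at 0.211 ± 0.104 CPM. All 19 lysine acetyltransferases were detected, with a median at percentile 48.8, among them GTF3C4 at 145 ± 4.02, CLOCK at 113 ± 5.67 and KAT2A at 62.7 ± 2.64 CPM. Of 17 bromodomain proteins, many but not all of which bind acetylated lysine, 16 were detected, and the median of all 17 lay at percentile 53.8. TRIM28 was at 743 ± 16.9, PBRM1 at 155 ± 4.55 and BRD2 at 138 ± 2.26 CPM, whereas the testis-specific BRDT had 1 count in all. Of 18 genes of acetyl-CoA and NAD metabolism, 15 were detected, with a median at percentile 62.7. ACLY, which makes cytosolic acetyl-CoA, was at 508 ± 8.60, citrate synthase (CS) at 207 ± 1.79 and NNMT, which methylates nicotinamide, at 83.1 ± 3.22 CPM. NMNAT3, ACSS1 and CD38 were not detected, at 0.0720 ± 0.0511, 0.174 ± 0.120 and 0.210 ± 0.0273 CPM.

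Members of the mesenchymal and matrix list ranged from very abundant to undetected. Of its 26 members, 17 were detected, and the median of all 26 lay at percentile 25.2. The intermediate filament gene VIM was at 4385 ± 149 CPM (n = 4), fibronectin (FN1) at 1163 ± 25.97 and SPARC at 504 ± 11.6 CPM. Of the stromal matrix genes LUM, POSTN and COL3A1, LUM had no count, which allows up to 0.0241 CPM, POSTN had 1 count and COL3A1 had 3 counts. Of 19 invasion proteases and inhibitors, 18 were detected, with a median at percentile 86.8. The membrane-bound collagenase MMP14 was at 1181 ± 11.4 and urokinase (PLAU) at 732 ± 18.9 CPM, and MMP10, with 4 counts, was the undetected member.

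**Figure D2:**
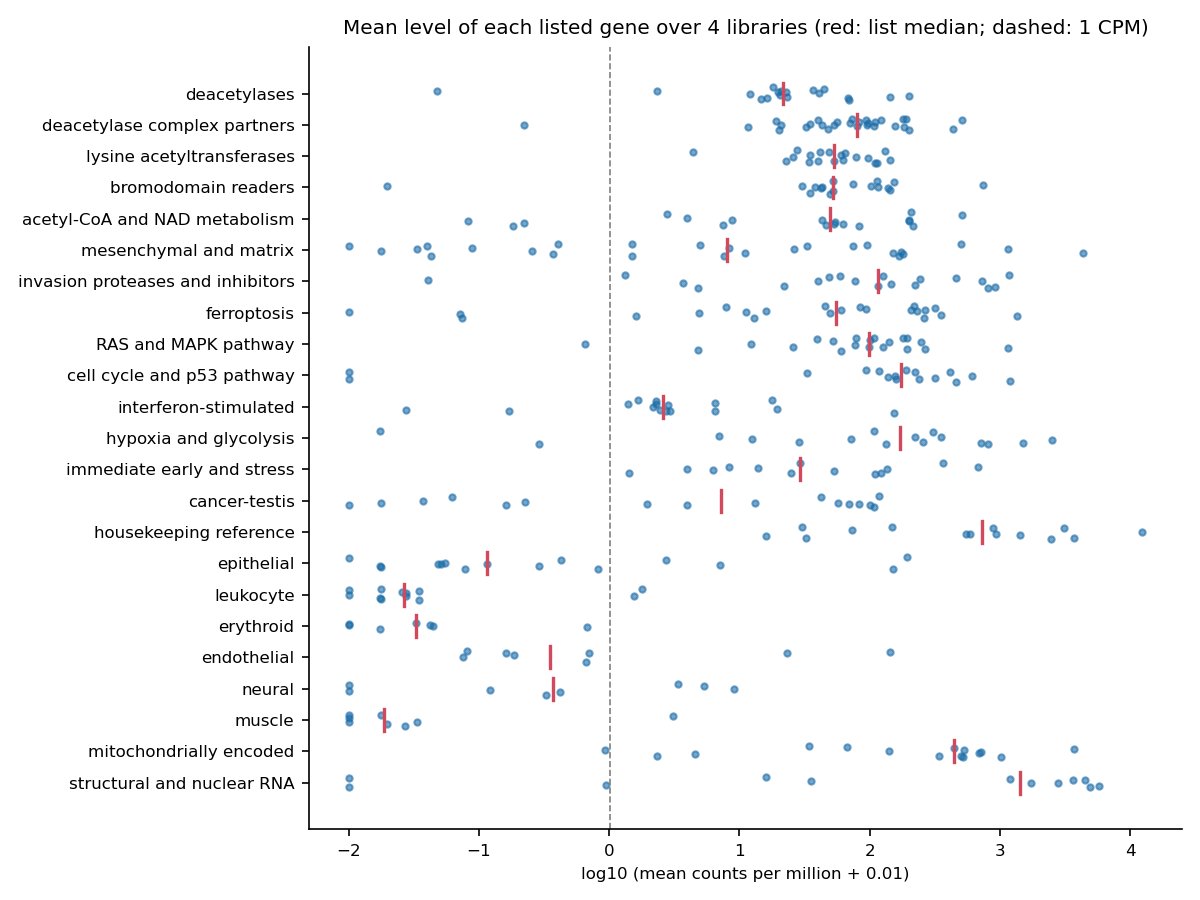
Mean CPM over 4 libraries, plotted as log10(CPM + 0.01), of each gene of the fixed lists, with a point per gene, a red bar at the list's median and a dashed line at 1 CPM; vertical scatter within a list only separates points. Markers of other cell types lie mostly left of the line, whereas all 14 reference genes and all 19 acetyltransferases lie right of it.

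Genes of growth and cell cycle control were abundant. In the RAS and MAPK list, 19 of 20 genes were detected, with a median at percentile 80.8, led per kilobase by PHLDA1 at 1153 ± 19.1 CPM (n = 4), the AP-1 subunit FOSL1 at 102 ± 6.95 CPM and the GTPase NRAS at 181 ± 6.75 CPM. DUSP6, a phosphatase that acts on ERK, was under the threshold at 0.639 ± 0.180 CPM. In the cell cycle and p53 list, 14 of 16 genes were detected, with a median at percentile 91.0. Cyclin D1 (CCND1) was at 1190 ± 19.7, TOP2A at 612 ± 8.91 and PCNA at 192 ± 9.74 CPM. The neighbouring cell cycle inhibitor genes CDKN2A (ENSG00000147889; GRCh38 chromosome 9, 21967753 to 21995301) and CDKN2B (ENSG00000147883; 22002903 to 22009363) had no count in any library, which allows up to 0.0241 CPM for each over the 4 libraries. The hypoxia and glycolysis list had 14 of 16 members detected and a median at percentile 84.9, with ENO1 at 2512 ± 52.4, LDHA at 1519 ± 61.8 and ALDOA at 812 ± 22.7 CPM. ADM had 1 count, and EGLN3 was at 0.281 ± 0.192 CPM.

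Of 22 genes linked to ferroptosis, a form of cell death driven by lipid peroxidation, 19 were detected, with a median at percentile 76.0. The transferrin receptor TFRC was at 1348 ± 66.6 CPM (n = 4) and the ferritin genes FTL and FTH1 at 354 ± 22.2 and 232 ± 14.3 CPM. ALOX15 had no count, which allows up to 0.0241 CPM, and ALOX12 and ALOX5 had 8 counts each. All 13 immediate early and stress genes were detected, with a median at percentile 69.6, led by the chaperone HSPA5 at 683 ± 16.2, ASNS at 364 ± 6.84 and JUN at 136 ± 2.59 CPM. Most interferon-stimulated genes were low, though the highest by CPM was at 155 CPM. Of 16, 14 were detected, and 9 reached 2 CPM in every library, and the median of all 16 lay at percentile 11.4. RIGI was at 17.6 ± 0.754 and ISG15 at 2.94 ± 0.793 CPM, whereas IFI44L had 2 counts and BST2 was at 0.161 ± 0.139 CPM. Of 16 cancer-testis genes, which are normally confined to germ cells, 10 were detected, and the median of all 16 lay at percentile 29.7. MAGEA6 was at 118 ± 5.93, CTAG2 at 108 ± 3.12 and MAGEA3 at 101 ± 3.59 CPM. MAGEA3 and MAGEA6 are near-identical copies, so the division of reads between them is uncertain. XAGE1A had no count, MAGEA4 had 1 count and MAGEA10 had 3 counts. The 14 reference genes were all detected, with a median at percentile 98.3, and EEF1A1, ACTB and GAPDH were at 12433 ± 346, 3690 ± 22.4 and 3128 ± 139 CPM. Without length scaling the median percentile was 45.9 for the immediate early and stress list, 18.4 for the cancer-testis list and 6.17 for the interferon-stimulated list. Among all protein-coding genes with any count, it was 36.9 for the interferon-stimulated, 50.1 for the cancer-testis and 46.9 for the mesenchymal and matrix list.

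Markers of other cell types were largely undetected, with exceptions. Of 15 epithelial markers, 4 were detected: KRT8 at 194 ± 1.83, KRT18 at 151 ± 2.46, OCLN at 7.07 ± 0.838 and CLDN4 at 2.71 ± 0.562 CPM (n = 4). Of 8 endothelial markers, 2 were detected, the receptor TIE1 at 142 ± 6.78 CPM and ROBO4 at 23.2 ± 1.78 CPM, and TEK was at 0.656 ± 0.251 CPM. Of 8 neural markers, 3 were detected, SNAP25 at 9.03 ± 0.587, GAD1 at 5.33 ± 0.615 and NEFL at 3.35 ± 0.162 CPM. Of 8 muscle markers, the embryonic myosin MYH3 alone was detected, at 3.10 ± 0.343 CPM, and ACTA1 and CKM had 3 counts and 1 count. Of 12 leukocyte markers, CSF1R at 1.78 ± 0.178 CPM and LYZ at 1.53 ± 0.193 CPM were detected, neither of them at 2 CPM, and NKG7 had 2 counts. None of 7 erythroid genes was detected at 1 CPM, and the highest, HBG2, was at 0.661 ± 0.153 CPM, with 4 counts each for HBA1 and HBB. Under 50% of each of these lists was detected, so a median percentile among detected genes is near 0 by construction. Among all protein-coding genes with any count, the median lay at percentile 19.4 for the endothelial, 17.1 for the neural and for the epithelial, 8.38 for the erythroid, 5.75 for the leukocyte and 2.98 for the muscle list.

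Protein-coding genes held 95.05% ± 0.113 (SD, n = 4) of the counts. The 10 genes with the highest mean CPM held 5.22% ± 0.128. After EEF1A1 these were RN7SK, the RNA that binds the elongation factor P-TEFb, at 5786 ± 642 CPM, the nuclear RNA MALAT1 at 4896 ± 276, COL6A3 at 4779 ± 105, the signal recognition particle RNA RN7SL1 at 4472 ± 561, VIM, ACTG1 at 4316 ± 145, AHNAK at 3711 ± 93.0, MT-CO1 at 3710 ± 450, and ACTB. The RN7SL1 counts were not whole in any library, so its value depends on how shared reads were divided. The 12 listed structural and nuclear RNAs held 2.46% ± 0.175 of the counts. Of them 9 were detected, and the median of all 12 lay at percentile 97.45. RPPH1, the RNA of ribonuclease P, was at 3646 ± 309 CPM, RNU4ATAC had no count, and the telomerase RNA TERC was at 0.929 ± 0.218 CPM. The RNU12 entry had no count either, but a second entry under that name, overlapping it on the same strand, had 230 counts, so the division of reads between them is uncertain. The 15 listed mitochondrially encoded genes held 0.873% ± 0.0904 and the 89 replication-dependent histone genes, whose messages lack poly(A) tails, 0.526% ± 0.0245. Of the mitochondrially encoded genes 14 were detected, with a median at percentile 99.8, among them MT-CO3 at 528 ± 71.1 and MT-ATP6 at 501 ± 56.5 CPM. The mitochondrial ribosomal RNA MT-RNR1 was at 0.913 ± 0.181 CPM in these ribosome-depleted libraries.

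The second question was how far the replicates differ. Across genes, which are not independent replicates, Pearson's r of log2(CPM + 1) lay between 0.9983 and 0.9986 for the 6 pairs of libraries, and Spearman's rho between 0.961 and 0.963, or between 0.997 and 0.998 over the 13895 detected genes. The counts of each pair differed by more than Poisson sampling noise, with a chi-square per degree of freedom between 2.93 and 4.13, so no pair was merged as 2 copies of 1 library. This does not show that the libraries come from separate cultures. The biological coefficient of variation, the spread between replicates beyond counting noise, was 0.0374 by edgeR, from a dispersion common to all genes. The square root of DESeq2's median dispersion over genes, a different summary, was 0.0614. For detected genes the median coefficient of variation of CPM was 4.85%. Among the 3 splits of the libraries into 2 against 2, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes for replicates 1 and 2 against 3 and 4, where 710 of 16442 genes had an unadjusted p under 0.05, against 822.1 expected by chance, and DESeq2 called 2. For replicates 1 and 3 against 2 and 4, edgeR called 2 genes, 703 had an unadjusted p under 0.05, and DESeq2 called 2. For replicates 1 and 4 against 2 and 3, edgeR called 16, 909 had such a p, and DESeq2 called 3. DESeq2's unadjusted p was under 0.05 for 162, 177 and 234 genes in the 3 splits, also against 822.1 expected. Its few calls are therefore not a like check on those of edgeR. Without a filter on low counts the highest of the 3 counts was 104.

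Of the 16442 genes tested, 56 were more variable between the libraries than the edgeR trend (Benjamini-Hochberg adjusted p under 0.05). The count was 25 without robust estimation of the prior, 242 without a filter on low counts and 21 without replicate 2. The antisense gene ENSG00000258377 had the lowest adjusted p by edgeR's F test, 2.6e-12, and was at 10.8, 7.66, 0.423 and 25.7 CPM in replicates 1 to 4. It lies within MGAT2 on the opposite strand. MGAT2, named after its values were seen, is also among the 56, at 69.1, 75.7, 82.6 and 55.6 CPM. MGAT2 was highest in replicate 3 and lowest in replicate 4, the reverse of the antisense gene, so the division of reads between them is uncertain. Of the 5 genes after ENSG00000258377 by p, 4 form 2 pairs of near-identical copies. SMIM11A was at 7.97, 1.80, 2.41 and 0.668 CPM and SMIM11B at 0.762, 6.86, 7.44 and 8.87 CPM, while their sum was 9.20 ± 0.595 CPM (SD, n = 4). RGPD5 was at 34.3 ± 14.8 CPM and RGPD6 at 87.3 ± 19.1 CPM, and their sum was 122 ± 6.03 CPM. Also among the 10 with the lowest p were RP11-717F1.2 at 10.8 ± 5.55 CPM, ENSG00000283029, a second annotation entry at the RN7SL1 locus, at 5.15 ± 2.93 CPM, CH507-24F1.2 at 4.18 ± 2.96 CPM, RMRP, the RNA of ribonuclease MRP, at 1732 ± 260 CPM, and RP11-386G11.10 at 60.6 ± 12.2 CPM. None of the deacetylase genes was among the 56.

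**Figure D3:**
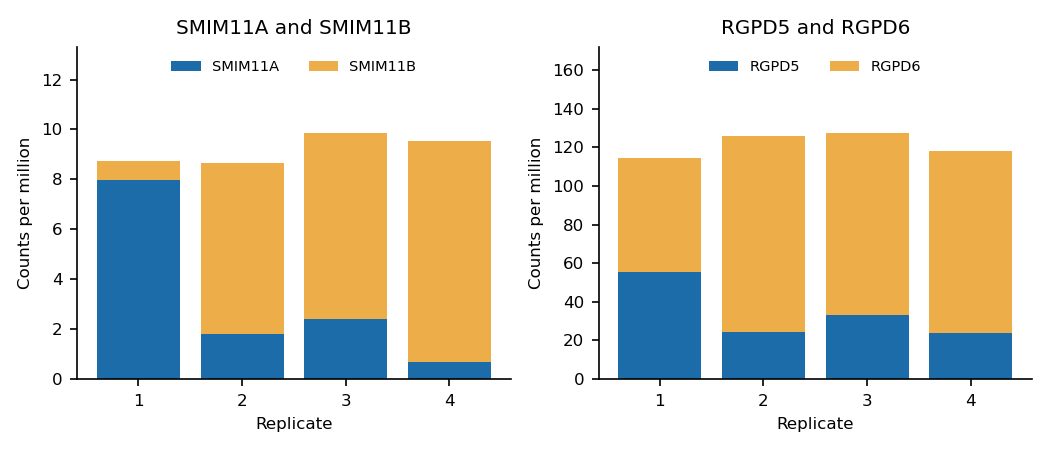
CPM of the copies SMIM11A and SMIM11B (left) and RGPD5 and RGPD6 (right) in each of the 4 replicates, stacked so that a bar's height is the sum of the pair. The division within each pair varies, from 7.97 to 0.668 CPM for SMIM11A, while the sums vary with a coefficient of variation of 6.47% and 4.96%.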

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

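Library totals, composition, the ratios and class shares of the deacetylases and the CPM of named genes with any count were tested for 1 library standing far from the other 3, by its gap to the nearest other value as a share of the range. Of 162 values, 17 passed the limit, and chance alone passes about 1 in 20. That rate does not apply to the 10 genes named for their spread between these libraries, 3 of which passed, nor to the 7 genes with a count in 1 library only, whose gap is 1 by construction. Of the other 145 values, 7 passed. Both tests of explanations in this part were set before their results were seen.

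In replicate 4, the number of genes at 1 CPM was 14345, against 14464 to 14481 in the others (gap 0.875 of the range). In replicate 1, the class I share of deacetylase abundance was 52.6%, against 53.9% to 54.1% (0.8975). The log2 ratio of HDAC3 to HDAC8 was 3.78 in replicate 3, against 3.96 to 3.98 (0.879). Replicate 3 also had the lowest CPM of MTA2, 103 against 113 to 114 (0.9505), and the highest of ISG15, 4.12 against 2.47 to 2.69 (0.8646), and NEFL, 3.59 against 3.24 to 3.28 (0.8898). CLDN4 was at 3.54 CPM in replicate 1, against 2.35 to 2.497 (0.8774). Of the genes more variable than the trend, RGPD6 was at 59.1 CPM in replicate 1, against 94.2 to 101 (0.8314). CH507-24F1.2 was at 8.55 CPM in replicate 4, against 2.38 to 3.39 (0.8367), and RP11-386G11.10 at 78.8 CPM in replicate 4, against 53.3 to 56.3 (0.8817). The genes with a count in 1 library only were BRDT in replicate 1, POSTN, ACTA1 and CKM in replicate 2, MAGEA4 and HOXD1 in replicate 3, and ADM in replicate 4 (each 1).

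The pattern weighed here is the 56 genes more variable than the trend. No library was the farthest from the other 3 in most of them. Replicate 1 was the farthest most often, for 26 genes or 46.4% (exact 95% interval 33.0% to 60.3%). Replicates 2, 3 and 4 were the farthest for 13, 9 and 8 genes. An even share among the 4 libraries would lie below the interval for replicate 1. That interval spans 50%, the bound set for this test, so 1 library standing apart remains open. The biological coefficient of variation was 0.0318 without replicate 1, against 0.0375 to 0.0401 without another replicate. Exact intervals here treat the 56 genes as independent, which genes that share reads are not, so the intervals may be too narrow. Reads shared between copies or overlapping genes are a candidate explanation: 85.7% of the 56 genes had no whole count in any library (exact interval 73.8% to 93.6%), against 27.0% of the other 16386 tested genes. A whole count is one with no fraction in the deposited table. This leaves 8 of the 56 genes without that sign, and the sign does not show that shared reads caused the spread where it is present. The 56 also hold 6 mitochondrially encoded genes, all highest in replicate 1, where the listed mitochondrially encoded genes held 1.004% of the counts against 0.799% to 0.854%, and 6 of the listed structural and nuclear RNAs, 4 of them highest in replicate 4. Of these 12 genes 8 had no whole count. A difference between libraries in the yield of such RNAs was not tested, and no biological explanation was tested, since the design has 1 group.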

How the results depend on the processing

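The APPRIS length was added after the data were seen. Of the 178 settings run for the main results, 149 were counted as unchanged, 27 as moved and 2 as reversed. A ratio counted as unchanged when its sign held, and other values when they stayed within their spread or within 1.5 times. The log2 ratio of SIRT6 to SIRT7 thus counted as unchanged without length scaling, where it fell from 1.26 to 0.12. Without length scaling the log2 ratios of HDAC1 to HDAC2 and HDAC6 to HDAC10 reversed, to -0.49 and 0.16. The means of the other 7 ratios kept their sign under every setting run. For SIRT3 to SIRT5, 1 of the 4 libraries had the other sign with the longest and with the APPRIS transcript. The sign-flip test of the ratios cannot pass 0.05 with 4 libraries. Class shares moved with the length definition: without length scaling class I took 52.1%, III 16.4%, IIa 25.5% and IV 0.297%. With the longest transcript class I took 56.8%, III 21.5%, IIa 14.7% and IIb 6.55%, and with the APPRIS transcript 50.3%, 22.3%, 21.3% and 5.88%. Class I stayed the largest. Detected deacetylases numbered 16 at 2 CPM, where HDAC11 fell below in replicate 2, and 17 in the other settings. Detected genes ranged from 12574 at 2 CPM to 15332 at 0.5 CPM. Leaving the structural RNAs out of the total gave 3.80% for the 10 most abundant genes, since some are structural, and 97.4% for protein-coding genes. The lowest correlation was 0.992 with a pseudocount of 0.1, 0.9972 over genes with a mean of at least 1 CPM, and 0.9983 to 0.9985 without 1 replicate. The coefficient of variation by edgeR was 0.0318 to 0.0401 with 1 replicate left out. The square root of DESeq2's median dispersion over genes, 0.0614, is a different summary from edgeR's common dispersion. The highest split count of 16 became 3 by DESeq2, 104 without a filter and 82 to 143 with 1 replicate left out, where 1 library stands against 2 and is assumed to vary like them. The count of 56 variable genes became 25 without robust estimation, 242 without a filter, and 21 to 48 without 1 replicate, lowest without replicate 2. The cause of these changes was not tested. Scaling by TMM or DESeq2 factors moved none of 125 named genes' mean CPM beyond its SD, and a total without mitochondrial and the 10 most abundant genes moved 59, all upward by 1.06 times. Depth leaves levels under 0.0241 CPM open.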

Other observations

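The collagen, keratin and HOX families were chosen after the data were seen. Of 44 collagen chain genes, 20 were detected. COL6A3 exceeded its partner chains COL6A1 and COL6A2 in length-scaled abundance, at 908 ± 36.8 (SD, n = 4) against 118 ± 5.87 and 124 ± 7.85. Other detected chains were COL4A2 and COL4A1 at 265 ± 11.3 and 178 ± 3.06 CPM, COL12A1 at 174 ± 4.05, COL13A1 at 127 ± 5.64, COL27A1 at 52.0 ± 1.11, COL5A1 at 33.0 ± 1.87 and COL1A1 at 1.48 ± 0.267 CPM. Of 55 keratin genes 8 were detected, and the hair keratin gene KRT81, at 853 ± 15.2 CPM, exceeded KRT8 and KRT18.

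Of 39 HOX genes, 24 were detected, with 7 of 11 in cluster A, 8 of 10 in B, 5 of 9 in C and 4 of 9 in D. HOXB9 had the highest CPM, at 42.2 ± 2.19 (n = 4), followed by HOXB2 at 17.4 ± 0.822, HOXA10 at 16.5 ± 1.23 and HOXA9 at 16.4 ± 0.604 CPM. In cluster D, HOXD8 to HOXD11 were detected, HOXD8 at 11.3 ± 1.69 CPM, while HOXD1, HOXD3 and HOXD4 had means of at most 0.0578 CPM. HOXD12, at 0.0449 ± 0.0707 CPM, and HOXD13, at 1.03 ± 0.306 CPM, were not detected either.

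Of the tests that follow, the one on copies of CDKN2A and CDKN2B and the one on gene length were chosen after the results they bear on were seen, and the bound on MTAP was set before, but the reading of its percentile after. CDKN2A and CDKN2B had no count in any library. Whether their reads were assigned to near-identical copies stays open, since the summed expected count of both genes, 0, restates the pattern. Loss of a chromosome segment that reaches MTAP, the next gene, may explain the zeros and was to be excluded by MTAP at 1 CPM or more. MTAP lay between 1.40 and 1.68 CPM, above that bound, but the bound took no account of a break inside the gene or of shared reads: MTAP lay at percentile 1.69 of detected protein-coding genes by CPM, its counts were not whole, and 135016 bases of it lie inside the overlapping gene ENSG00000264545, also named after the values were seen. KLHL9, at 148 ± 4.71 CPM, and DMRTA1, at 9.41 ± 0.607 CPM, were detected on either side and were chosen after their values were seen, so a loss and silencing of both genes cannot be told apart from RNA counts.

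The order of HDAC1 and HDAC2 depends on whether counts are divided by length. The lowest log2 ratio of HDAC1 to HDAC2 over 3 length definitions was 1.47, with an SD of 0.05, against -0.49 in CPM. The lowest of the 3 is the ratio that defines the pattern, so it does not test gene length bias in read counts, which stays open. All 3 definitions come from 1 annotation, and if the cells use a shorter HDAC2 transcript than annotated, the ratio would be smaller. Transcript use was not analysed here, and no biological explanation was tested.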
